A study of Lactiplantibacillus plantarum WCFS1 with 18 samples.

How the data were processed

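Total RNA of Lactiplantibacillus plantarum WCFS1 was measured on 18 arrays of 10807 probes, labelled with the dye Cy5 per the labels. The deposited table gives 1 intensity per probe and array on a linear scale, and the values differ between arrays in their median (48.1 to 469 units), so they were taken as not normalized between arrays. Between 3.04% and 6.32% of the values per array lie at or below 0, which a background subtraction would give. The method of that subtraction, the scanner and the feature extraction are not given in the sources used here. The labels' protocols describe labelled genomic DNA as a possible normalizer, and whether the deposited intensity was set against it is not stated. No other sample columns were used.

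Probes were named through the platform annotation, which pairs 1146 probes (10.6%) with 1 gene symbol each. They cover 334 symbols and 337 genes, since 3 symbols (aroE, carB and murC) each stand for 2 gene IDs. A gene has a median of 3 named probes, 10 genes have 1, and the other probes are unnamed here. Gene positions were not used here. A table of gene names of another strain was not used.

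MRS culture 3 correlated with MRS culture 1 at 0.0150 over all probes as deposited and at 0.895 after its values were moved up by 1 row, where MRS cultures 1 and 2 correlate at 0.903. In blocks of 1000 rows the moved array gave 0.882 to 0.911, and no other array had a correlation beyond 0.0233 in size when moved by 1 row. The moved values were used throughout, a choice made after the data were seen, and the values as deposited are an alternative.

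Values at or below 0 were left out, the rest taken to log2 and normalized by quantiles over all 10807 probes, because the arrays' medians differ by over 0.5 on the log2 scale. Probes of a gene were averaged, then arrays of one mouse, which gave 14 biological samples in 5 groups. Mice are separate animals. That the numbered cultures were grown separately is not stated, so p-values of the broth comparisons measure the spread between these samples, which can be technical. The fit shares the spread of a gene over all 5 groups, so p-values of the cecum comparisons rest in part on that spread too. limma 3.58.1 in R 4.3.3 fitted all 5 groups together (lmFit and eBayes, prior degrees of freedom 3.79), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The same fit was run on all probes, with p-values adjusted over the probes tested in each comparison; quantile normalization over all probes largely sets the balance of higher and lower there, and no such fit was run without it. For the comparison with every one of 3 broths, the 3 differences had to share a sign and the largest p was adjusted. Of 40 gene lists, 15 had at least 4 measured genes and were tested with camera at a preset correlation of 0.01 and with an estimated one. The camera test sets the genes of a list against the other measured genes. A list can therefore pass while its own median is near 0. Figures were drawn with matplotlib in Python.

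The groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes, in the comparisons of cecum with broth, chow cecum with chow broth, western with chow cecum and chow broth with MRS, the 10 called genes with the largest positive and the 10 with the largest negative difference among those whose sides do not overlap in any sample. It adds up to 3 called members per list, takes 3 genes per direction in the other comparisons, and lets the text summarise the rest.

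The fit was tested on simulated data with the real spread of the 337 genes, in 5 runs with 50 genes changed 2-fold and 50 changed 4-fold. For chow cecum against chow broth it recovered 76.4% of the 2-fold and 98.8% of the 4-fold changes, and 3.31% of its calls were false. For western against chow cecum it recovered 68.4% and 97.2% with 4.61% false, and for chow broth against MRS 74.4% and 98.8% with 3.13% false. The simulated genes varied independently, with the same spread in every group. Real genes of a list are correlated (estimated at 0.729 for ribosomal proteins), and the lower probe agreement of the western arrays was not simulated. These rates may therefore not carry over to the real comparisons. Alternatives were values without normalization, equalized array medians, the dimmest 25% of genes left out, all arrays with the mouse as a random block, the first or last array of each mouse, medians of probes, fits of 2 groups alone, eBayes with trend and robust, a log2 difference of at least 1, a replicate block, 50 units added before log2, MRS culture 3 as deposited, the western arrays left out, and each biological sample left out in turn. The cut at a log2 difference of 1 was applied to counts of genes and not to single genes, whose calls count as kept there. The number of alternatives that lose a call is thus too low for genes with a smaller difference. Genes in the dimmest 25% have no value under that alternative. With all arrays in the fit, arrays of one mouse had a correlation of 0.332 within the fit. CDM with lactose, which the design text names, was not analysed here.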

Results

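Transcript levels of the lactic acid bacterium Lactiplantibacillus plantarum WCFS1 were measured on 18 arrays in the cecum of mice that carried this strain as their only known microbe, and in broth cultures. The mice were germ-free until inoculation at 6 weeks of age and were sampled 15 days later. The cecum samples came from 4 mice on chow (7 arrays) and 2 mice on a western-style diet (3 arrays). The cultures were grown in MRS, a rich laboratory medium (3 cultures), in a broth made from chow (3 cultures), or in a chemically defined medium (CDM) with glucose (2 cultures). The labels give the growth phase of all cultures as exponential and give none for the cecum samples. Growth phase and site therefore cannot be told apart in any comparison of cecum with broth. The median intensity per array ran from 48.1 to 469 units. The number of arrays limits the precision, and a level below is a mean over mice or cultures, never over arrays of one mouse. Each array held 10807 probes, of which 1146 could be named, for 337 genes. Differences are log2 differences with the standard error of the limma fit, and adjusted p-values are limma's, adjusted over the 337 genes.

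In the cecum of mice on chow, the bacterium carried far more transcript of adhE (gene ID 1061605), the bifunctional enzyme that turns acetyl-CoA into ethanol, than in a broth made from the same food. The mean log2 level of adhE was 13.18 ± 0.53 (SD, n = 4 mice) against 6.99 ± 0.50 (SD, n = 3 cultures), a 73.2-fold difference (log2 6.19 ± 0.33 SE, adjusted p = 3.2e-08). The arabinose isomerase gene araA rose 8.87-fold (3.15 ± 0.23), the Clp ATPase gene clpL 7.53-fold (2.91 ± 0.16), the nucleoside diphosphate kinase gene ndk 6.70-fold (2.74 ± 0.33) and pdhA, for a pyruvate dehydrogenase subunit, 4.83-fold (2.27 ± 0.25). The genes that put D-alanine on teichoic acids of the cell wall fell, dltD with a log2 difference of -2.53 ± 0.30, dltB with -2.39 ± 0.27 and dltA with -2.04 ± 0.23. The isoleucyl-tRNA synthetase gene ileS had the largest drop, with a log2 difference of -2.82 ± 0.26.

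Among the fixed lists, citrate use moved as a whole in this comparison. All 5 measured genes of citrate lyase and its activation were higher in the chow cecum and none lower, and all 5 also passed when adjusted over the list alone. The largest differences were those of citE (0.99 ± 0.20), citF (0.94 ± 0.17) and citD (0.89 ± 0.21), and the list passed the camera test (adjusted p = 0.0133 with the preset correlation, adjusted p = 0.265 with an estimated correlation). Of 12 chaperone, protease and heat shock genes, 5 rose, none fell and 7 were not called, with the same 5 adjusted over the list alone. Beside clpL, these were led by the chaperone genes dnaK (1.79 ± 0.39) and grpE (1.73 ± 0.34), and the camera test gave adjusted p = 0.0179, or adjusted p = 0.657 with an estimated correlation. Chow broth itself was lower than MRS broth in dnaK (-1.80 ± 0.41) and grpE (-1.79 ± 0.36). Those calls were lost under 3 and 1 of 20 alternatives. Against MRS broth, 1 of the 12 genes was higher in the chow cecum, with a median of -0.01 and camera adjusted p = 0.0755. Against CDM with glucose, 1 was higher and 2 lower, with a median of -0.29 and camera adjusted p = 0.429. Of 6 ATP synthase genes, 2 fell and 4 were not called, with 4 lower when adjusted over the list alone. The 2 that fell were atpB (-1.36 ± 0.33) and atpF (-0.89 ± 0.29), with a camera adjusted p = 0.0326, or adjusted p = 0.657 with an estimated correlation. The list no longer passed without mouse 29, without chow broth culture 2, with the first array of each mouse or with MRS culture 3 as deposited.

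Other groups moved in single members. Of the 34 genes of amino acid biosynthesis, 3 rose and 4 fell (3 and 4 when adjusted over the list alone), and the fall was led by 3 genes of the shikimate pathway to aromatic amino acids, aroA (-2.41 ± 0.21), aroB (-1.58 ± 0.32) and aroE with gene ID 1062246 (-1.39 ± 0.18). The asparagine synthetase gene asnA (-1.87 ± 0.30), the lysine biosynthesis gene lysA (-1.79 ± 0.20) and the homocysteine methyltransferase gene mmuM (-2.34 ± 0.16) fell as well. These 3 genes are not in the list of 34. Chow broth itself was higher than MRS broth in aroA (2.28 ± 0.22), aroB (1.48 ± 0.35), this aroE (2.16 ± 0.19) and mmuM (1.85 ± 0.17). Of the genes in these sentences, only asnA and lysA are among the 10 lower in the chow cecum than in every broth. The phosphate transporter genes pstC (1.85 ± 0.37) and pstB (1.83 ± 0.26, from 1 probe) rose, as did the peptidase gene pepT (2.02 ± 0.19) and the enolase gene eno (1.81 ± 0.32), which was the 1 called gene of 5 in glycolysis. The thiol peroxidase gene tpx (-2.17 ± 0.28) and the mechanosensitive channel gene mscL (-1.88 ± 0.37) fell. Of 51 ribosomal protein genes only rpsU was called (-1.51 ± 0.36, with 0 called when adjusted over the list alone), and the list's median difference was -0.08. Of 15 aminoacyl-tRNA synthetases, ileS and leuS (-0.91 ± 0.20) fell and 13 were not called, with the same number lower when adjusted over the list alone.

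**Figure D1:**
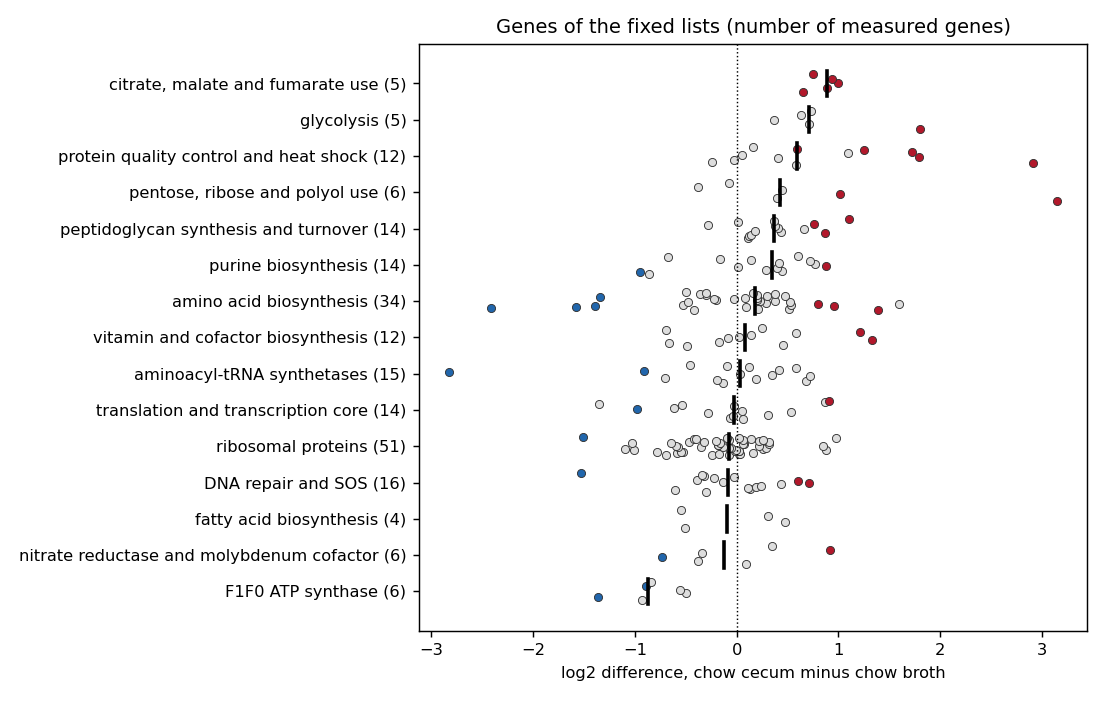
Log2 difference of each measured gene of the 15 tested lists, chow cecum minus chow broth (horizontal axis), with called genes in red (higher) or blue (lower), other genes in grey and the list median as a black bar. All 5 citrate genes lie to the right of 0, while the 51 ribosomal protein genes centre on a median of -0.08.

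In all, 71 of 337 genes were called between chow cecum (4 mice) and chow broth (3 cultures), 41 higher and 30 lower, and 113 had an unadjusted p under 0.05. Over all 10685 tested probes, named or not, 842 were higher and 896 lower. The calls of eno, dnaK, grpE and citE were lost on values left without normalization and with MRS culture 3 used as deposited, under which 27 genes were called, and those of pstC, citF and citD were lost without normalization. Of the genes that fell, atpF lost its call under 11 of 20 alternatives, among them the loss of any 1 chow broth culture. The calls of atpB, rpsU, leuS and mscL were lost with MRS culture 3 as deposited, those of atpB and rpsU also without chow broth culture 2 and that of leuS also with medians of probes. No MRS culture is on either side here, so MRS culture 3 can enter only through the normalization and the spread shared in the fit. The median of the heat shock list turned to -0.13 without normalization. The split was 7 higher and 61 lower without normalization and 29 higher and 37 lower with array medians equalized, and 39 genes were called with a log2 difference of at least 1.

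Against MRS broth, adhE (5.94 ± 0.33), araA (3.20 ± 0.23) and clpL (2.92 ± 0.16) were again the genes that rose most in the chow cecum. The genes that fell most were fabI (-4.15 ± 0.47) and fabF (-3.03 ± 0.38), for the enoyl reductase and a condensing enzyme of fatty acid synthesis, and dltB (-2.94 ± 0.27). Of 15 aminoacyl-tRNA synthetases, 9 were lower and 6 not called (10 lower when adjusted over the list alone), with camera adjusted p = 0.00941, or adjusted p = 0.292 with an estimated correlation. Of the 5 citrate genes, 3 were higher (4 when adjusted over the list alone), with camera adjusted p = 0.00184, or adjusted p = 0.126 with an estimated correlation. Of 6 genes for the use of pentoses, ribose and polyols, 2 were higher (2 adjusted over the list alone), with camera adjusted p = 0.0148, or adjusted p = 0.292 with an estimated correlation. Of 34 amino acid biosynthesis genes 3 were higher and 1 lower (3 and 1 adjusted over the list alone), with camera adjusted p = 0.0388, or adjusted p = 0.292 with an estimated correlation, and a median of 0.08 whose sign turned under some alternatives. The median over all genes was -0.30, so the amino acid list passed by lying above the other genes. The fit called 82 genes, 24 higher and 58 lower, against 765 higher and 627 lower of 10705 tested probes, named or not. That split was 11 and 118 without normalization and 25 and 144 with medians equalized. Leaving out mouse 26 gave 126 calls, leaving out MRS culture 1 gave 46, and MRS culture 3 as deposited gave 27, while fits of these 2 groups alone gave 44, the first array of each mouse gave 50 and a log2 difference of at least 1 gave 52.

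Against CDM with glucose, adhE (6.52 ± 0.38), araA (3.34 ± 0.26) and pdhA (2.95 ± 0.28) rose most in the chow cecum, and asnA (-4.95 ± 0.34), fabI (-4.33 ± 0.54) and dltD (-3.45 ± 0.35) fell most. Of the 51 ribosomal protein genes, 38 were lower and none higher (40 lower when adjusted over the list alone), with a median of -1.50 and camera adjusted p = 0.000895, or adjusted p = 0.688 with an estimated correlation. Of 6 genes of nitrate reductase and its molybdenum cofactor, 4 were higher (4 when adjusted over the list alone), with camera adjusted p = 0.000895, or adjusted p = 0.158 with an estimated correlation. Of 6 pentose, ribose and polyol genes 3 were higher (3 adjusted over the list alone), with camera adjusted p = 0.000895, or adjusted p = 0.158 with an estimated correlation. Of 15 aminoacyl-tRNA synthetases 9 were lower (10 adjusted over the list alone), with camera adjusted p = 0.0234, or adjusted p = 0.433 with an estimated correlation. The fit called 156 genes, 35 higher and 121 lower, or 11 and 187 without normalization. Over all 10592 tested probes the split was 832 and 850. With CDM culture 1 alone, after culture 2 was left out, 39 genes were called, MRS culture 3 as deposited gave 40, and a fit of these 2 groups alone gave 62.

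The mouse cecum on chow differed from every one of the 3 broths in one direction for 20 genes, 10 higher and 10 lower, and for 387 of 10477 tested probes, named or not, 316 higher and 71 lower. The higher ones were adhE, clpL, araA, pdhA, ndk, eno, pstB, pepT, the folate synthesis gene folK and the plantaricin bacteriocin gene plnF. The smallest of the 3 differences was still 5.94 for adhE, 2.91 for clpL and 3.15 for araA. The lower ones were the 3 dlt genes, ileS, leuS, lysA, asnA, def, nrdE and dnaX, with smallest differences of -2.39 for dltB, -2.53 for dltD and -2.04 for dltA. All 20 are named because they make up the count, after their values were seen. The largest p of the 3 contrasts, adjusted over all genes, was 1.07e-07 for adhE and 0.0465 for plnF. Against chow broth alone the plnF call (1.01 ± 0.27) was lost under 5 of 20 alternatives, among them no normalization, MRS culture 3 as deposited and the loss of chow broth culture 2, and the folK call under 2 of 20. The split was 5 and 17 without normalization and 8 and 13 with medians equalized, and with MRS culture 3 as deposited 7 genes were called.

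**Figure D2:**
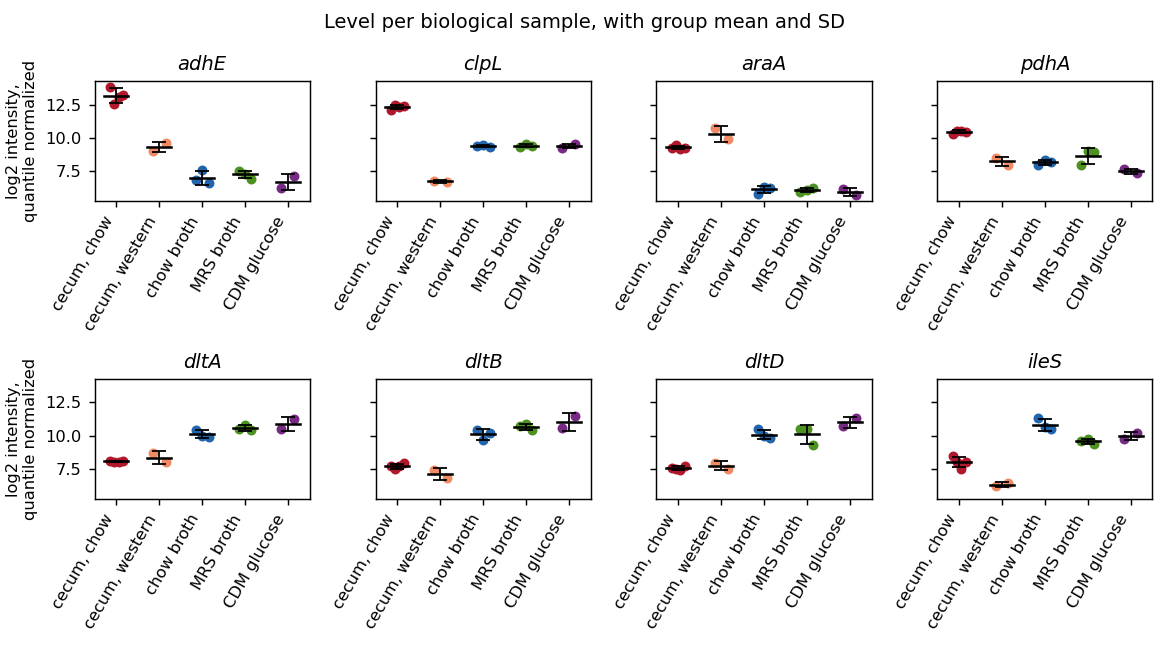
Log2 intensity after quantile normalization (vertical axis) of 8 genes in each mouse or culture of the 5 groups, with points for samples, a bar for the group mean and whiskers for the SD. In chow cecum, adhE averaged 13.18 against 6.67 to 7.25 in the 3 broths, and dltB averaged 7.70 against 10.09 to 11.02.

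The broths also differed from each other. In chow broth, against MRS broth, 4 genes of aromatic amino acid synthesis were higher, aroA at 2.28 ± 0.22, aroE (gene ID 1062246) at 2.16 ± 0.19, aroB at 1.48 ± 0.35 and aroF at 1.25 ± 0.32, as were mmuM (1.85 ± 0.17) and tpx (1.28 ± 0.30). The second aroE (gene ID 1062996, -0.41) and aroD (-0.09) were not called. The aromatic genes were not tested as a list, and the calls of aroB, aroF and tpx were lost under 4, 5 and 3 of 20 alternatives. The fatty acid synthesis genes fabI (-3.60 ± 0.51) and fabF (-3.51 ± 0.40), the trehalose regulator gene treR (-2.98 ± 0.47) and the glycyl-tRNA synthetase genes glyQ (-2.41 ± 0.35) and glyS (-1.78 ± 0.25) were lower. The calls of fabI, treR and glyS were lost with MRS culture 3 as deposited. The pyrimidine genes pyrE (-4.48 ± 1.11) and pyrF (-3.85 ± 0.97) and carB with gene ID 1062982 (-4.34 ± 1.05), for carbamoyl phosphate synthase, had the largest means and the largest errors. MRS cultures 1 and 2 held pyrE at 13.47 and 12.65, MRS culture 3 at 7.57, and the 3 chow broth cultures at 6.56 to 6.88. The calls of these 3 genes were lost when MRS culture 1 or 2, or any chow broth culture, was left out, and that of pyrF also in a fit of the 2 groups alone and with 50 units added. Of 14 peptidoglycan and division genes, 8 were lower (11 when adjusted over the list alone), with camera adjusted p = 0.00999, or adjusted p = 0.627 with an estimated correlation. Of 15 aminoacyl-tRNA synthetases, 7 were lower and ileS was higher (1.24 ± 0.27), against 9 lower and 1 higher adjusted over the list alone (the ileS call was lost with MRS culture 3 as deposited), with camera adjusted p = 0.0461, or adjusted p = 0.627 with an estimated correlation.

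The list of 34 amino acid biosynthesis genes includes carB with gene ID 1062982. Of the 34 genes, 5 were higher and 3 lower (5 and 3 adjusted over the list alone). Their median of 0.01, whose sign turned under some alternatives, lay above the -0.38 of all genes. The list passed by lying above the other genes, with camera adjusted p = 0.00999, or adjusted p = 0.295 with an estimated correlation. Of 6 nitrate reductase and molybdenum cofactor genes 1, narH (0.76 ± 0.23), was higher (1 adjusted over the list alone), with camera adjusted p = 0.00999, or adjusted p = 0.295 with an estimated correlation. The narH call was lost under 11 of 19 alternatives, among them the loss of any 1 MRS or chow broth culture, with a difference as low as 0.05. The chow broth and MRS comparison (3 cultures each) called 68 genes, 15 higher and 53 lower, against 434 higher and 310 lower of 10620 tested probes, named or not. Without normalization it called 23, 12 higher and 11 lower, and with MRS culture 3 as deposited 14. Leaving out single cultures gave 18 without chow broth culture 1, 21 without chow broth culture 3, 29 without chow broth culture 2, 19 without MRS culture 1 and 39 without MRS culture 2.

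In CDM with glucose, against MRS, asnA (3.59 ± 0.36), aroA (2.89 ± 0.25) and aroE with gene ID 1062246 (2.82 ± 0.21) were higher and treR was lower (-3.19 ± 0.52). The other called genes were purB, aroF and hisI, all higher, named after their values were seen. The call of treR was lost in a fit of the 2 groups alone and with MRS culture 3 as deposited. Of 51 ribosomal protein genes 0 were called, over all genes or adjusted over the list alone, while their median was 0.86 (camera adjusted p = 0.000189, adjusted p = 0.622 with an estimated correlation). Of 6 nitrate reductase and molybdenum cofactor genes 0 were called over all genes and 1 was lower when adjusted over the list alone, with a median of -0.42 (camera adjusted p = 0.0137, adjusted p = 0.569 with an estimated correlation). The comparison called 7 genes (2 against 3 cultures), while 60 had an unadjusted p under 0.05, and without MRS culture 3 it called 16. Of 10534 tested probes, named or not, 108 were higher and 20 lower.

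Chow broth against CDM with glucose had asp1 (1.77 ± 0.29), rpsU (1.76 ± 0.43) and narH (1.30 ± 0.26), for a nitrate reductase subunit, among its higher genes, and fabI (-3.79 ± 0.57), fabF (-3.58 ± 0.45) and asnA (-3.08 ± 0.36) among its lower ones. Of 51 ribosomal protein genes, 30 were lower and 1 higher (35 and 1 adjusted over the list alone), with camera adjusted p = 0.00309, or adjusted p = 0.63 with an estimated correlation. Of 6 nitrate reductase and molybdenum cofactor genes, 2 were higher (4 adjusted over the list alone), with camera adjusted p = 2.49e-05, or adjusted p = 0.0659 with an estimated correlation. The fit called 113 genes, 11 higher and 102 lower, against 272 higher and 262 lower of 10530 tested probes, named or not. The calls of asp1, rpsU and narH were lost with MRS culture 3 as deposited, and that of rpsU also without either CDM culture or normalization. It called 17 without CDM culture 2, 47 without chow broth culture 1, 54 without chow broth culture 3, 10 with MRS culture 3 as deposited and 19 without normalization.

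In the cecum on the western diet, ribosomal protein genes and genes of the translation core were measured far lower than in the cecum on chow. The elongation factor gene tuf (-6.29 ± 0.23), the RNA polymerase subunit gene rpoZ (-5.77 ± 0.89), clpL (-5.60 ± 0.18), the aldolase gene fba (-5.18 ± 0.28) and adhE (-3.87 ± 0.38) fell. Of 51 ribosomal protein genes, 50 fell and none rose (51 lower when adjusted over the list alone), with a median of -2.80 (camera adjusted p = 1.46e-08, adjusted p = 0.55 with an estimated correlation). Of 12 chaperone and heat shock genes, 11 fell (12 when adjusted over the list alone), with camera adjusted p = 0.0013, or adjusted p = 0.55 with an estimated correlation. Of 14 genes of the translation and transcription core, 11 fell (11 adjusted over the list alone), with camera adjusted p = 0.0116, or adjusted p = 0.55 with an estimated correlation. Of 15 aminoacyl-tRNA synthetases, 8 fell and 2 rose (8 and 2 adjusted over the list alone), with a median of -0.65, and the list did not pass (camera adjusted p = 0.899, adjusted p = 0.981 with an estimated correlation). Of 5 glycolysis genes, 4 fell and 1 rose (4 and 1 adjusted over the list alone), the latter being eno (1.31 ± 0.36, named after its value was seen). The list did not pass (camera adjusted p = 0.116, adjusted p = 0.55 with an estimated correlation). Amino acid biosynthesis moved the other way after quantile normalization, with 20 of 34 genes higher and 5 lower (20 and 5 adjusted over the list alone), among them trpD (2.07 ± 0.22) and hisG (1.92 ± 0.33), with camera adjusted p = 1.53e-08, or adjusted p = 0.026 with an estimated correlation. The bacteriocin genes plnF (2.07 ± 0.31) and plnE (1.94 ± 0.28) were higher as well, and plnJ, the other one measured, was not called. Without normalization the amino acid list turned, from a median of 1.06 to -0.82. The calls of trpD, hisG, plnF and plnE were lost there, and eno turned to -0.15. The eno call was also lost with medians of probes, with MRS culture 3 as deposited and without western mouse 65.

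The 3 western arrays stood apart in quality. On them, 36.3% to 40.8% of the log2 variance of the named probes lay between genes, against 63.5% to 90.9% on the 15 other arrays and a 95th percentile of about 33% with shuffled gene names. Their gene levels correlated with those of the chow broth arrays at 0.025 to 0.10 (Pearson r across genes, which are not independent replicates), against 0.710 or more on the other arrays. The diet comparison (2 mice against 4) called 218 genes, 56 higher and 162 lower, or 0 and 291 without normalization. Over all 10723 tested probes 2666 were higher and 2203 lower, a balance that quantile normalization over all probes largely sets.

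**Figure D3:**
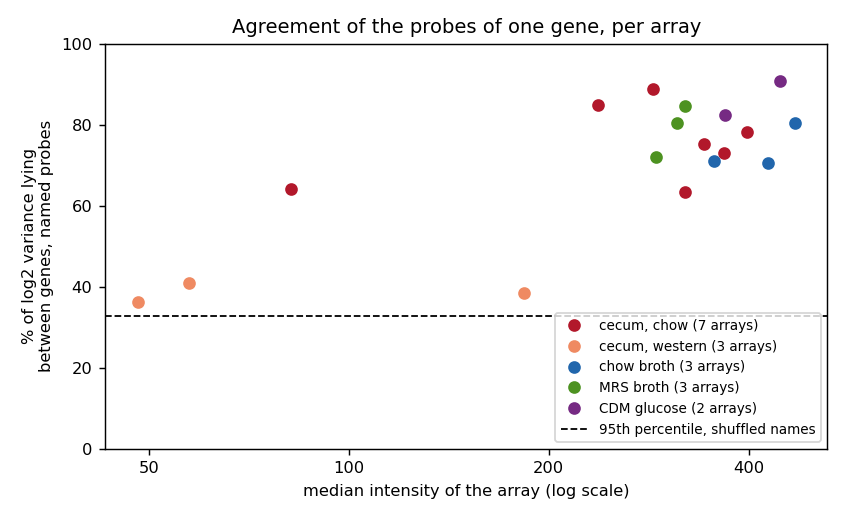
Percent of the log2 variance of the named probes lying between genes (vertical axis) against the median intensity of the array (horizontal log axis) for the 18 arrays, coloured by group, with the mean 95th percentile under shuffled gene names as a dashed line. The 3 western arrays lie between 36.3% and 40.8%, and the 15 others at 63.5% or more.

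Against the 3 broths taken with equal weight, the western cecum had araA (4.25 ± 0.23), plnF (3.45 ± 0.29) and eno (3.32 ± 0.33) highest, while rpoZ (-6.61 ± 0.81), tuf (-6.12 ± 0.21) and the ribosomal gene rpsF (-5.92 ± 0.52) fell most. All 51 ribosomal protein genes were lower (51 when adjusted over the list alone), and 17 of 34 amino acid biosynthesis genes were higher and 6 lower (17 and 6 adjusted over the list alone). The ribosomal list had camera adjusted p = 3.2e-08, or adjusted p = 0.503 with an estimated correlation, and the amino acid list adjusted p = 1.35e-07, or adjusted p = 0.0393 with an estimated correlation. The pentose, ribose and polyol list (3 of 6 higher, 3 adjusted over the list alone) had adjusted p = 0.00394, and the nitrate reductase and molybdenum cofactor list (3 of 6 higher, 3 adjusted over the list alone) adjusted p = 0.00995, each with adjusted p = 0.24 with an estimated correlation. All 14 translation and transcription core genes were lower (14 adjusted over the list alone, adjusted p = 0.00714), as were 11 of 12 chaperone and heat shock genes (11 adjusted over the list alone, adjusted p = 0.0127), each with adjusted p = 0.503 with an estimated correlation. Without normalization the amino acid, pentose and nitrate reductase lists turned to lower medians (-1.58, -1.52 and -1.36), and the amino acid median was -0.22 with the dimmest genes left out. Of 10441 tested probes, named or not, 3065 were higher and 2828 lower. The comparison called 262 genes, 62 higher and 200 lower, or 3 and 310 without normalization, on the 3 arrays whose probe agreement is given above.

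The cecum of both diets with equal weight, against the 3 broths, had adhE (4.28 ± 0.25), araA (3.74 ± 0.17), eno (2.67 ± 0.23), plnF (2.41 ± 0.20), pstB (1.81 ± 0.19) and argF (1.70 ± 0.29) highest. Among called genes whose cecum and broth samples did not overlap, the largest drops were those of dltB (-3.19 ± 0.20), ileS (-2.97 ± 0.19), dltD (-2.75 ± 0.22), mscL (-2.45 ± 0.28), atpB (-2.42 ± 0.25) and dltA (-2.32 ± 0.17). Of 6 genes for the use of pentoses, ribose and polyols, 4 were higher (4 adjusted over the list alone), with camera adjusted p = 0.000939, or adjusted p = 0.18 with an estimated correlation. All 51 ribosomal protein genes were lower (51 when adjusted over the list alone), with camera adjusted p = 1.26e-07, or adjusted p = 0.521 with an estimated correlation. Amino acid biosynthesis had 16 of 34 genes higher and 6 lower (15 and 6 adjusted over the list alone), with camera adjusted p = 2.35e-05, or adjusted p = 0.121 with an estimated correlation. The nitrate reductase and molybdenum cofactor list had 4 of 6 genes higher (4 adjusted over the list alone, adjusted p = 0.00632, adjusted p = 0.2 with an estimated correlation), and the citrate list 2 of 5 (2 adjusted over the list alone, adjusted p = 0.0472, adjusted p = 0.29 with an estimated correlation). All 14 translation and transcription core genes were lower (14 adjusted over the list alone, adjusted p = 0.00632, adjusted p = 0.521 with an estimated correlation), as were all 6 ATP synthase genes (6 adjusted over the list alone, adjusted p = 0.0472, adjusted p = 0.555 with an estimated correlation). The citrate list had a median of 0.09, where that of all genes was -0.58. The amino acid median of 0.28 turned to -0.11 without the western arrays, -0.26 with the dimmest genes left out and -1.05 without normalization. The pentose, nitrate reductase and citrate lists turned without normalization as well, and citrate without CDM culture 1. The calls of pstB and argF were lost without normalization, and that of argF also with medians of probes. The 3 western arrays, with 36.3% to 40.8% of variance between genes, enter all of these shifts. This comparison of 6 mice with 8 cultures called 251 genes, 61 higher and 190 lower, or 4 and 301 without normalization. Over all 10441 tested probes the split was 2663 and 2787. Without the western arrays it called 114, 37 higher and 77 lower, and with MRS culture 3 as deposited 151.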

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

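The tests on the western arrays as a whole, on MRS culture 3, on other splits of the samples and on the spread between samples around level-matched genes were chosen after the results were seen, while the level-matched test of the 2 gene lists was written down before its result was known.

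The cecum-against-broth differences of the 2 diets differed from each other for 218 genes, since the broths cancel in the diet comparison. Little sequence-specific signal on the western arrays may account for part of this: at most 40.8% of their variance lies between genes, below every other array. Displaced rows over a whole western array are argued against, since the lowest rank correlation of a western array with a chow broth array is 0.376. The displaced MRS array as deposited reached at most 0.00754 by the same measure. A displacement of only some of the rows was not tested. Arrays with flat levels would lower bright genes and raise dim ones, but random lists matched on broth level had a median of -2.19 (95% range -2.67 to -1.98) against -2.80 for ribosomal proteins, at percentile 0.440, and of 0.07 against 1.06 for amino acid biosynthesis, at percentile 100. Those ranges treat the members of a list as separate, so the excess over matched genes was also set against the spread between samples. It was -0.61 (95% interval -1.41 to 0.19) for ribosomal proteins, which leaves flat levels open as their explanation. For amino acid biosynthesis it was 0.71 (0.46 to 0.96), so broth level alone leaves part of the shift unaccounted for. Genes were not matched on their level in chow cecum, the other side of the comparison, so flat levels stay open there too. An effect of the diet stays open, untested and in the same 2 mice as the array quality.

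MRS culture 3 as deposited resembled no other array (r from -0.00838 to 0.0381). A displacement by 1 row is the candidate explanation, since the move raised r with MRS culture 1 to 0.895. A failed hybridisation is argued against by the 80.6% of variance lying between genes after the move. No biological explanation was tested for this pattern.

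Other splits of the same samples gave fewer genes than the 71 called between chow cecum and chow broth. Of 35 splits only the real one reached that count, and the highest other gave 13. A share here can be no smaller than 1 of 35, so chance is made less likely and not excluded. For chow cecum against MRS broth, 2 of 35 splits gave as many as the real 82, and the highest other gave 98, so chance cannot be excluded by this count. That split sets mouse 26 with the MRS cultures against mice 27, 29 and 30, and its cause was not tested. For chow broth against MRS broth (68 genes, highest other 1), the 10 splits are too few for a share under 0.05. For the cecum of both diets against broth, 1 of 100 relabellings reached 251, the real one, and the highest other gave 181. The relabellings also moved the western samples, and 181 is above the 114 genes that the real comparison called without the western arrays. The count can follow where the western samples fall, so chance is not excluded by it.

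In 5 of 72 tested genes and list means, 1 mouse on chow lay far from the other 3, where chance gives about 1 in 20. The gap as a share of the range was 0.873 for argF, 0.933 for folK and 0.861 for thiE, where mouse 27 was highest, 0.853 for tpx, where it was lowest, and 0.913 for pepT, where mouse 29 was lowest. The array of mouse 27 correlated with the other chow mice at 0.629 to 0.807 over rows 7001 to 10000, against 0.910 or more elsewhere, and 24 of its named probes were at or below 0.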

How the results depend on the processing

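The alternatives with MRS culture 3 as deposited, without the western arrays, with 50 units added and with the last array of each mouse were chosen after seeing the data. Of 224 recomputed counts, 188 stayed within 1.5 times the reported one. Of 2542 recomputed values of named genes, 2298 kept direction and side of the threshold, 239 kept direction only and 5 reversed. The 127 of them under the cut at a log2 difference of 1 repeat the main fit and were kept by construction. Of 808 list values 694 kept direction and side, 82 passed no longer, 9 passed newly and 23 reversed. Of those 82, 34 came with an estimated correlation, 7 with the dimmest genes left out and 3 without the western arrays. Between chow cecum and chow broth, 19 of 46 named genes stayed past the threshold under every alternative run for them. The same held for 6 of 13 between the diets, 8 of 28 between chow broth and MRS and 10 of 12 for the cecum of both diets. The western arrays, with median intensities of 48.1 to 184 units and at most 40.8% of variance between genes, limit what the diet comparison can resolve. For all values in the next paragraphs the cause was not tested, except where fewer samples or a stricter threshold entered by construction. In comparisons without MRS broth, MRS culture 3 as deposited can enter only through the normalization and the spread that the fit shares over all 5 groups.

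Without normalization the count was 129 for chow cecum against MRS, 23 for chow broth against MRS and 19 for chow broth against CDM. The median of all genes then shifted to -2.40 between the diets and -0.65 between chow cecum and chow broth, from -0.63 and 0.04. List medians reversed for amino acid biosynthesis in the cecum of both diets (-1.05), the western cecum against broth (-1.58), western against chow cecum (-0.82) and chow cecum against MRS (-0.04), for pentose use (-0.72 on both diets, -1.52 on western), nitrate reductase (-0.60 and -1.36), citrate use on both diets (-1.23) and heat shock in chow cecum against chow broth (-0.13). The genes hisH (-0.18) and eno (-0.15) reversed between the diets, and recO (-0.15) in chow cecum against chow broth.

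With medians equalized the count was 169 for chow cecum against MRS, and the amino acid median of chow broth against MRS was 0, as with 50 units added (0). With the dimmest genes left out, CDM against MRS gave 3 genes, and the amino acid median was -0.26 on both diets and -0.22 on western. The first array of each mouse gave 50 genes for chow cecum against MRS, with an amino acid median of -0.06, and 43 for chow broth against MRS. Fits of only the 2 groups gave 44 against MRS and 62 against CDM for chow cecum. A log2 difference of at least 1 gave 142 genes for the cecum of both diets, 39 against chow broth and 52 against MRS for chow cecum, and 40 for chow broth against MRS. With an estimated correlation 0 lists passed in chow cecum against chow broth, where 3 did.

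MRS culture 3 as deposited gave 151 genes for the cecum of both diets, 27 for chow cecum against chow broth, 27 against MRS, 40 against CDM and 7 against every broth, 145 between the diets, 14 for chow broth against MRS and 10 against CDM. The amino acid median was then -0.04 for chow cecum and -0.11 for chow broth against MRS, and in the latter ftsZ (0.21) and pfkA (0.25) reversed. Without the western arrays the cecum against broth gave 114 genes and an amino acid median of -0.11.

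Leaving out 1 mouse or culture at a time gave 2 to 5 lists in chow cecum against chow broth, and 46 to 126 genes for chow cecum against MRS, 39 to 183 against CDM, 18 to 57 for chow broth against MRS, 17 to 92 against CDM and 5 to 16 for CDM against MRS. The other ranges were 50 to 68 for chow cecum against chow broth, 15 to 21 against every broth, 188 to 226 between the diets, 223 to 263 for western and 228 to 255 for both diets against broth. The amino acid median ran from -0.07 to 0.14 for chow cecum and from -0.02 to 0.07 for chow broth against MRS, and the citrate median on both diets from -0.01 to 0.19. Where 1 western mouse or CDM culture was left, it is assumed to vary like the other groups.

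With the culture number as a replicate block among the broths, chow broth against MRS gave 49 genes, CDM against MRS 6 and chow broth against CDM 88. The 7 pairs of cultures with the same number correlated at -0.373 to 0.321 after group means were removed, 2 of them over 0.1, so the numbers were not taken to pair the cultures.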

Other observations

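Further fixed lists in chow cecum against chow broth moved in few members. Of 14 peptidoglycan and division genes 3 were higher, among them murG (1.11 ± 0.31) and ftsZ (0.87 ± 0.26), with 3 higher when adjusted over the list alone and camera adjusted p = 0.118. The call of murG was lost under 6 of 20 alternatives and that of ftsZ under 9. Of 12 vitamin and cofactor genes, folK (1.33 ± 0.26) and the thiamine gene thiE (1.21 ± 0.31) were higher (both also adjusted over the list alone), with calls lost under 2 of 20 and 4 of 19 alternatives. Of 6 genes for pentoses, ribose and polyols, araA and the regulator gene rbsR (1.01 ± 0.22) were higher, and camera gave adjusted p = 0.116. In purine synthesis purF was higher (0.88 ± 0.28) and guaB lower (-0.95 ± 0.23) among 14 genes, with calls lost under 13 of 19 and 2 of 20 alternatives. Of 16 DNA repair genes uvrC was lower (-1.53 ± 0.21), and recJ (0.71 ± 0.20) and recO (0.60 ± 0.18) were higher, with calls lost under 0, 5 and 11 of 20 alternatives (recO turned to -0.15 without normalization). Of 14 genes of the translation and transcription core tuf was higher (0.91 ± 0.21) and rpoB lower (-0.98 ± 0.31), with calls lost under 2 and 9 of 20. Of 6 nitrate reductase and molybdenum cofactor genes narI was higher (0.92 ± 0.28) and mobB lower (-0.73 ± 0.20), with calls lost under 10 and 5 of 19. The iron transporter gene feoB was higher (0.81 ± 0.16), and its call and that of rbsR were lost under 2 alternatives each. None of 4 fatty acid synthesis genes was called by limma in this comparison, over all genes or adjusted over the list alone. Of the called genes in this paragraph, only araA and folK are among the 20 that differed from every broth in the same direction.

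Arrays of one mouse were not always the closest pairs. Over all probes, the 3 same-mouse pairs of chow arrays correlated at 0.892 to 0.923, and the 18 pairs from different mice at 0.777 to 0.958. The difference between the 2 arrays of mouse 26 correlated across genes with that of mouse 30 at 0.631, with that of mouse 29 at 0.411 and with the difference of the 2 CDM cultures at 0.483. The difference of mouse 29 correlated with that of mouse 30 at 0.101, with that of the CDM cultures at 0.124 and with that of MRS cultures 1 and 2 at 0.169. That of mouse 30 correlated with those of the CDM and MRS cultures at 0.483 and 0.481. For the MRS difference, r was 0.472 with mouse 26 and 0.465 with the CDM cultures. Differences were array a minus b, CDM culture 2 minus 1 and MRS culture 1 minus 2. Genes are not independent replicates, and no explanation was tested for this.

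Of the 10 genes higher in chow cecum than in every broth, 5 were called lower on the western diet than on chow (clpL, adhE, ndk, pdhA and pepT), 3 higher (plnF, eno and araA) and 2 neither way (folK and pstB), after quantile normalization and on the western arrays whose probe agreement is given in the report. Over all 337 genes, 162 were called lower and 56 higher in the same comparison. The 10 genes were picked as high on the same chow cecum arrays, which favours lower values on the western diet. Without normalization 0 genes were called higher between the diets, and eno turned to -0.15.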
